A study of Mus musculus with 32 samples.

How the data were processed

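Liver RNA of 32 male wild-type C57BL/6 mice was hybridised to 1-colour (Cy3) Agilent arrays of design 028005, 1 mouse per array. For each array the authors deposited the scanner output of Agilent Feature Extraction. Per the file headers its processed signal is an intensity after background subtraction and detrending within the array, with no scaling between arrays. Per the file headers the version was 11.0.1.1, whereas the submitters' notes name version 9.1. The authors also deposited a table of log2 values that were normalised between arrays and had a batch effect removed before limma. The method and the batch were not named. That table holds 16795 values per array for 15148 probes, and each of its 32 columns correlated best with its own array (smallest r over probes 0.813). It served as an alternative only.

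Each array held 62976 spots, of which 3671 were controls, and 55681 distinct probes. The share of probes well above background ranged from 43.4% to 58.1% (24191 to 32341 probes), the 75th percentile of the signal from 128 to 302.5, and 0 spots were saturated. Control spots and spots the scanner software marked as outliers were left out, and the spots of a probe were averaged. Values were log2 of the processed signal minus the array's 75th percentile. Probes were kept if they were well above background on all arrays of at least 1 group (30488 probes). The files give no gene symbols, so each probe's RefSeq identifier was looked up in a table of RefSeq genes (assembly GRCm38.p6), which gave a symbol to 26582 probes and none to 29099. No genome came with the data, so no coordinates are given. The brightest probe stood for each gene, which left 23110 genes, 14082 of them with a symbol. For 228 probes a value was missing on at least 1 array.

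The 12 groups (2 schedules, 3 times of day, 2 ages) were fitted as group means with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with the slide as a random block (8 slides of 4 arrays, estimated correlation 0.244) and moderated variances (2.26 prior degrees of freedom). The fit used generalised least squares with limma's variance moderation, and its t values differed from limma's own by at most 8e-14 over 11 comparisons. For 17 comparisons, Benjamini-Hochberg adjusted p under 0.05 counted as a call. They were the schedules compared at each age over the mean of the 3 times and at each time, time of day within each of the 4 combinations of schedule and age, schedule by time of day at each age, the ages compared within each schedule, and schedule by age. All adjusted p values below come from this limma test unless another is named. Each gene had 1 error estimate over all 12 groups, so lists from different comparisons are not independent. This alone can raise the number of shared genes above that of independent lists. Changes are log2 with their standard error (SE). For tests over 3 times the range is the highest minus the lowest fitted group mean, and for an interaction it is the range of the difference between schedules. A list of genes was tested with limma's camera on the moderated statistics, with a preset correlation of 0.01 and, as an alternative, an estimated correlation, over 31 lists in the 5 comparisons of means. The lists, comparisons, tests, threshold, named-gene rule and first set of alternatives were chosen before the data were examined.

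Genes were named by a rule. For each comparison of means these were the 10 higher and 10 lower genes of largest change among those called and changed the same way at all 3 times. For each comparison at 1 time they were the 3 higher and 3 lower genes of largest change, and for each test over the 3 times the 6 genes of largest range. Added to these were all core clock genes and up to 4 members of each list, called members of largest change first. Symbols that are not plain gene symbols were not named. A gene named in one comparison may also be given with its value in another. Where a gene was not well above background on any array of a group, its fold is given as a lower bound, with the arrays of that group raised to the background level, or not at all when both sides were near it. The background level was the lowest signal of any probe well above background on that array. Groups with at least 1 such array kept all their values, so the bound is approximate. Each replicate is another mouse, so the number of arrays limits the precision.

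The pipeline was tested on simulated data with the same groups and slides. In the comparison of schedules at 12 weeks it called 76% of genes changed 1.5-fold and 92% of genes changed 2-fold, and 5 of its 173 calls (2.9%) were unchanged genes. At a single time with 3 mice per group it called 32% and 73%, and 6 of 111 calls (5.4%) were unchanged genes. The simulated genes varied independently of each other, with a correlation only within slides. In the real arrays marker genes of other tissues moved together, so the share of unchanged genes among real calls may differ.

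Alternatives set before the data were examined were normexp background correction with offset 50 (on median spot and background signals, since the files hold no mean signals), quantile normalisation, no filter on dim probes, only probes well above background on all 32 arrays, no block, slide as a fixed block, scan day as a random block, the mean of a gene's probes, the authors' deposited table with no block, the replicate number as the block, limma with trend and robust variances, the estimated correlation in camera, and each mouse left out in turn. Alternatives added after the data were seen were a 75th percentile over probes well above background on all arrays, leaving out the 10 arrays whose mean pancreatic acinar marker level lay over 2 log2 units above the median array, covariates for the acinar and skeletal muscle marker means, and leaving out all ZT2 arrays. Slide as a fixed block gives the within-slide values.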

Results

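The deposited data are liver transcriptomes of 32 male wild-type C57BL/6 mice, measured on 1-colour Agilent arrays with 1 mouse per array. In the steady schedule, 16 singly housed mice stayed in 12 h light and 12 h dark. Under chronic jet lag, 16 singly housed mice were moved from 4 weeks of age between 2 rooms whose light onset differed by 8 h. Livers were taken at zeitgeber time (ZT, hours after light onset) 2, 10 and 18, at 12 and 30 weeks of age, which made 12 groups. Each group held 2 mice at ZT2 and 3 mice at ZT10 and ZT18. The labels do not say how ZT in the jet-lagged mice relates to their last shift. Between 24191 and 32341 of 55681 probes per array were well above background, and 23110 genes were tested. Mouse numbers name separate animals, and the number of arrays limits the precision.

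The first question was how liver gene expression varied over the day in each schedule. In the steady schedule core clock genes were among those with the largest ranges. At 12 weeks Ciart, a repressor of the clock's activating complex, varied at least 34.7-fold and was highest at ZT10 (n = 8, adjusted p = 1e-08), since it was not well above background at ZT2 and ZT18. Dbp, a clock-driven transcription factor, ranged over 6.55 log2 units, and Nr1d1, the repressor REV-ERB alpha, varied at least 24.1-fold, both highest at ZT10. Arntl, which encodes the activator BMAL1, ranged over 5.75 and was highest at ZT2. Of 22 measured core clock genes, 19 varied with time of day in steady mice at 12 weeks and 19 at 30 weeks (19 and 19 adjusted over the list alone). In jet-lagged mice, 9 varied at 12 weeks and 5 at 30 weeks (14 and 7 adjusted over the list alone). The range of Dbp was 0.76 at 12 weeks and 0.69 at 30 weeks in jet-lagged mice, which did not pass the test, against 6.55 and 6.22 in steady mice. Without 1 mouse it reached at most 1.64 (mouse 2 of the jet-lagged ZT2 group) at 12 weeks and 1.65 (mouse 1 of that group) at 30 weeks. Nfil3, a repressor of the same target sites as DBP, ranged over 2.72 and 2.94 in steady mice and over 0.26 and 0.10 in jet-lagged mice (at most 0.58 without mouse 1 and 0.71 without mouse 2 of the ZT2 groups). Per2, a repressor that also responds directly to feeding and light cues, ranged over 3.16 and 1.82 in steady mice and over 3.25 and 1.69 in jet-lagged mice, all past the threshold, and its interaction with schedule did not pass (adjusted p = 0.778 and 0.972). Its jet-lagged range at 30 weeks was 1.02 without mouse 2 of the ZT2 group, where the call was lost, and 2.36 without mouse 1.

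**Figure D1:**
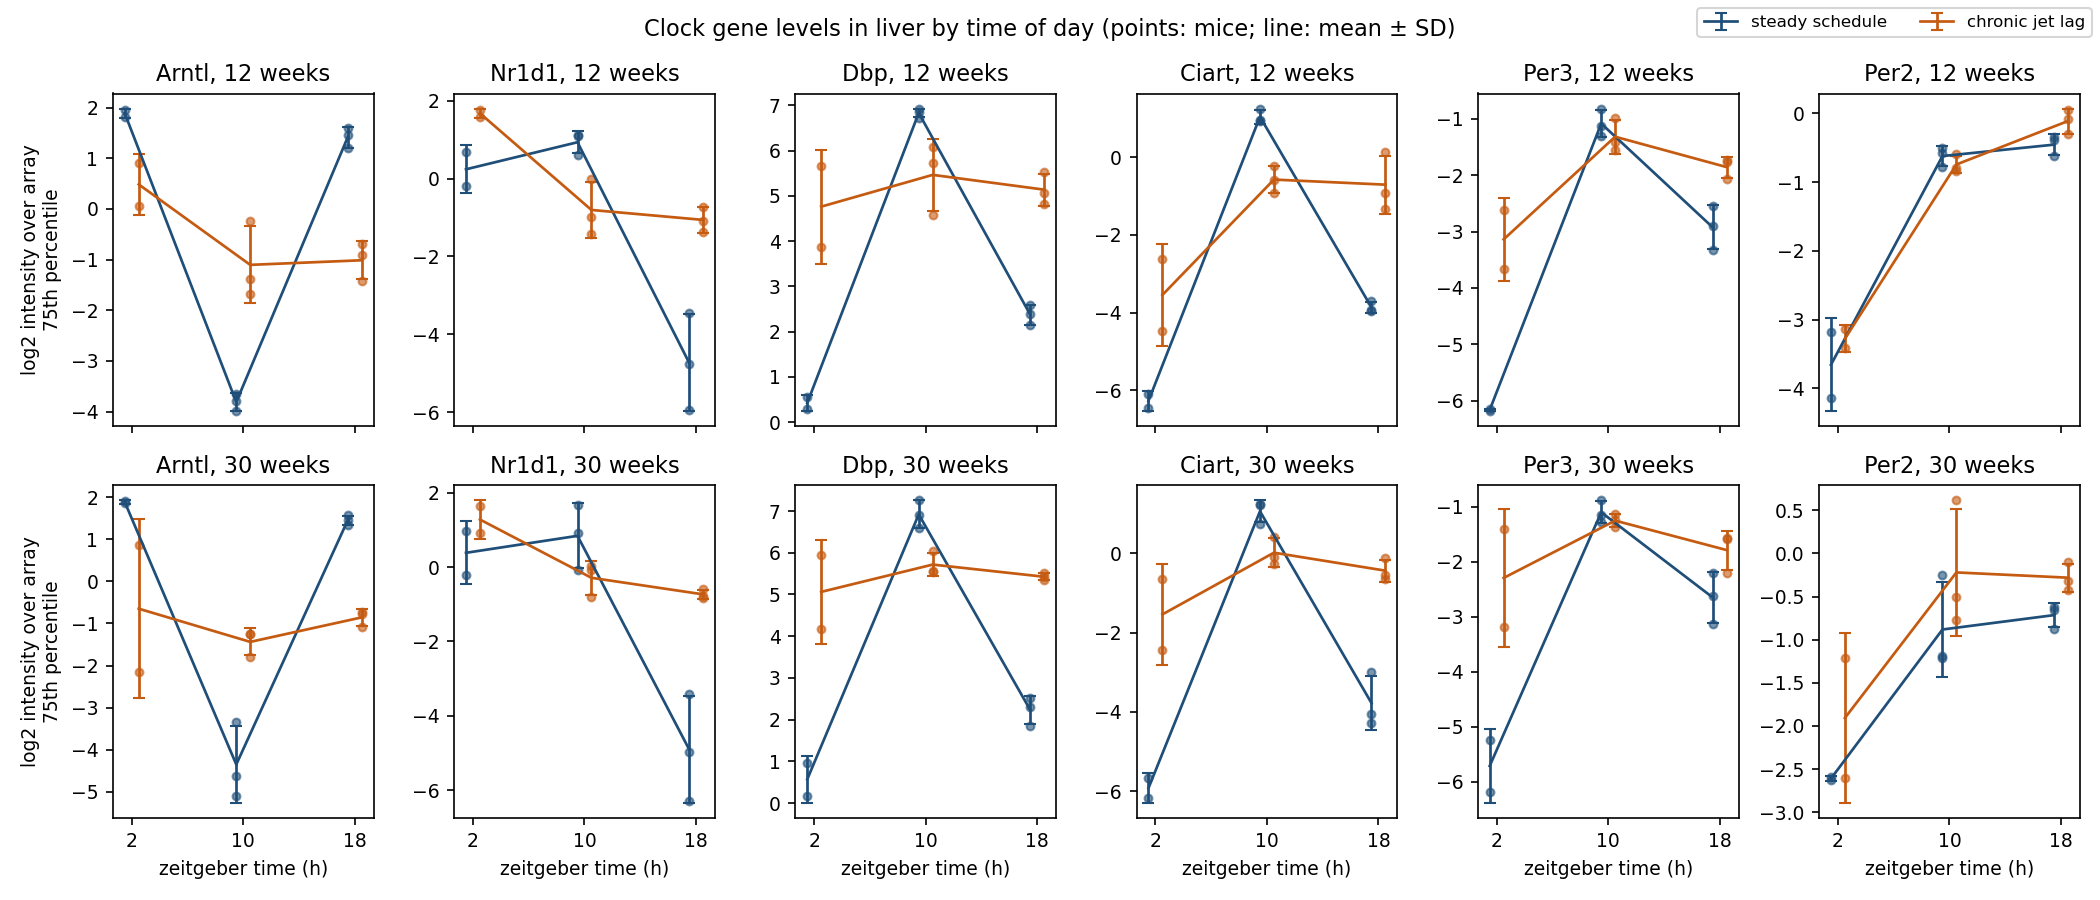
Levels of 6 core clock genes in liver, as log2 intensity over the array's 75th percentile, against zeitgeber time at 12 weeks (top) and 30 weeks (bottom). Points are mice and lines are group means with SD (2 mice at ZT2, 3 at ZT10 and ZT18). In the fit Dbp ranged over 6.55 in steady mice and 0.76 in jet-lagged mice at 12 weeks, while Per2 ranged over 3.16 and 3.25.

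Outside the clock, steady mice showed daily variation in stress, sterol and glucose genes. Of 20 heat shock and temperature genes, 16 varied at 12 weeks and 13 at 30 weeks (19 and 17 adjusted over the list alone), among them the chaperones Hsp90aa1 and Hsph1, with ranges of 2.16 and 2.08 at 12 weeks and highest levels at ZT18. Of 28 genes of the unfolded protein response, 19 and 14 varied (21 and 21 adjusted over the list alone), led by Creld2, an endoplasmic reticulum stress protein, with 2.32 and 2.16. Of 26 bile acid genes, 13 and 11 varied (15 and 11 adjusted over the list alone). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, ranged over 2.45 and 1.96. Of 28 glucose metabolism genes, 18 and 15 varied (20 and 15 adjusted over the list alone). Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, ranged over 3.32 and 4.19, highest at ZT2. In jet-lagged mice fewer of these genes passed, but counts of separate tests do not test the difference between schedules. The counts were 9 and 3 heat shock genes (12 and 10 adjusted over the list alone) and 9 and 4 genes of the unfolded protein response (17 and 18). For bile acid genes the counts were 3 and 2 (4 and 3), and for glucose genes 7 and 9 (7 and 10). Fatty acid and triglyceride synthesis went the other way at 30 weeks. In jet-lagged mice 19 of 32 genes varied (26 adjusted over the list alone), against 9 in steady mice (12). The jet-lagged ZT2 group at this age was 2 mice, the same pair with the raised acute phase genes described below. Thrsp, an inducer of lipogenesis, ranged over 3.63 in jet-lagged mice and 1.93 in steady mice, and Elovl6, a fatty acid elongase, over 3.40 and 0.45, the last not past the threshold (0.10 and 0.83 without mouse 2 or 1 of the steady ZT2 group).

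Across all genes, 4052 varied with time of day in steady mice at 12 weeks and 2587 at 30 weeks, against 1308 and 857 in jet-lagged mice. At 12 weeks 1051 of the 4052 were highest at ZT2, 1481 at ZT10 and 1520 at ZT18. Of the genes called in steady mice, 1888 were called at both ages, where independent lists would share 453.6, and 1581 of them were highest at the same time. The 4052 genes had a median range of 0.68 in steady mice and 0.34 in jet-lagged mice, and the difference between schedules itself passed for 426 of them (10.5%). Genes chosen in 1 schedule favour that schedule. The 1308 genes called in jet-lagged mice at 12 weeks had a median range of 0.83 there and 0.61 in steady mice. Skeletal muscle genes were among the largest ranges, which goes with the muscle marker level of each group (mean over both ages 0.77 in steady mice at ZT18 against -2.68 at ZT2 and -3.00 at ZT10). They were Ckmt2, a muscle creatine kinase, at 12 weeks (range 6.49) and Tnnc2, a troponin, at 30 weeks (range 6.63), both in steady mice and highest at ZT18. In jet-lagged mice at 30 weeks the perinatal myosin Myh8 varied at least 343-fold, highest at ZT18. Slc2a4, the glucose transporter of muscle and fat, ranged over 5.30 there. With slide as a fixed block the counts were 2685 and 1501 in steady mice and 550 and 492 in jet-lagged mice, and with marker covariates 2577, 1638, 1115 and 232.

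The interaction of schedule with time of day asks directly which daily profiles differed between schedules. At 12 weeks 446 genes passed and at 30 weeks 431. Of the 22 core clock genes, 12 passed at 12 weeks and 13 at 30 weeks (17 and 16 adjusted over the list alone). Jet-lagged mice had Dbp higher by 4.33 ± 0.53 at ZT2 and by 2.85 ± 0.42 at ZT18 at 12 weeks, while at ZT10 the difference was -1.45 ± 0.42 (n = 2 against 2 at ZT2 and 3 against 3 at the other times, adjusted p = 0.000337, 0.000462 and 0.0786). Arntl was higher by 2.71 ± 0.50 at ZT10 and lower at ZT18, with a change of -2.49 ± 0.50. At 30 weeks the same genes behaved alike, with Arntl at 2.75 ± 0.50 at ZT10 (well above background on 1 of 3 steady arrays) and -2.18 ± 0.50 at ZT18 and Dbp at 4.47 ± 0.53 at ZT2. Both ages called 165 interactions, against 8.3 for independent lists. Other interactions at 12 weeks were Cyp26b1, which degrades retinoic acid (range 4.32, highest in jet-lagged mice at ZT10), and the cholesterol exporter Abcg8 (1.88, at ZT18). Nat8f5, a male-biased acetyltransferase, passed at both ages with ranges of 2.22 and 2.06. With slide as a fixed block 85 and 59 interactions passed, including 8 of the 12 and 5 of the 13 clock genes. With the acinar-rich arrays left out, 181 and 22 passed, including 2 of the 12 and 0 of the 13 clock genes in limma (12 and 13 at unadjusted p under 0.05).

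At 30 weeks the interaction also held lipid, glucose and acute phase genes. Of 32 genes of fatty acid and triglyceride synthesis, 11 passed at 30 weeks (22 adjusted over the list alone) and 3 at 12 weeks (7). Fasn, the fatty acid synthase, had an interaction range of 3.26, the desaturase Scd1 3.07 and Elovl6 3.05, each with the jet-lagged difference highest at ZT18. At ZT2 Scd1 fell by 2.18 ± 0.37 in jet-lagged mice, and at ZT18 its difference was 0.90 ± 0.29 (adjusted p = 0.00278 and 0.0925). Of 28 genes of glucose metabolism and insulin response 5 passed (9 adjusted over the list alone). Igfbp1 had an interaction range of 4.48, whose call was lost in 3 of 32 fits without 1 mouse, and it fell by 4.17 ± 0.70 at ZT2. Pnpla5, a triglyceride lipase, was at least 4.87-fold lower at ZT2, since it was not well above background in either jet-lagged mouse. Of 31 acute phase genes, 7 passed at 30 weeks (14 adjusted over the list alone). The serum amyloid genes Saa1 and Saa2 were higher in jet-lagged mice at ZT2 by 5.70 ± 0.87 and 5.62 ± 0.88. Lcn2, an iron-binding acute phase protein, was higher by 3.59 ± 0.63 and Orm3, an orosomucoid, by 3.21 ± 0.47 (n = 2 against 2, adjusted p = 0.00368 and 0.00102). The lipid, glucose and acute phase differences at ZT2 all come from the same 2 jet-lagged mice. Their means of Saa1 and Saa2 were 9.98 and 9.25, against at most 6.08 in steady mice. A link between these gene groups was not tested.

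**Figure D2:**
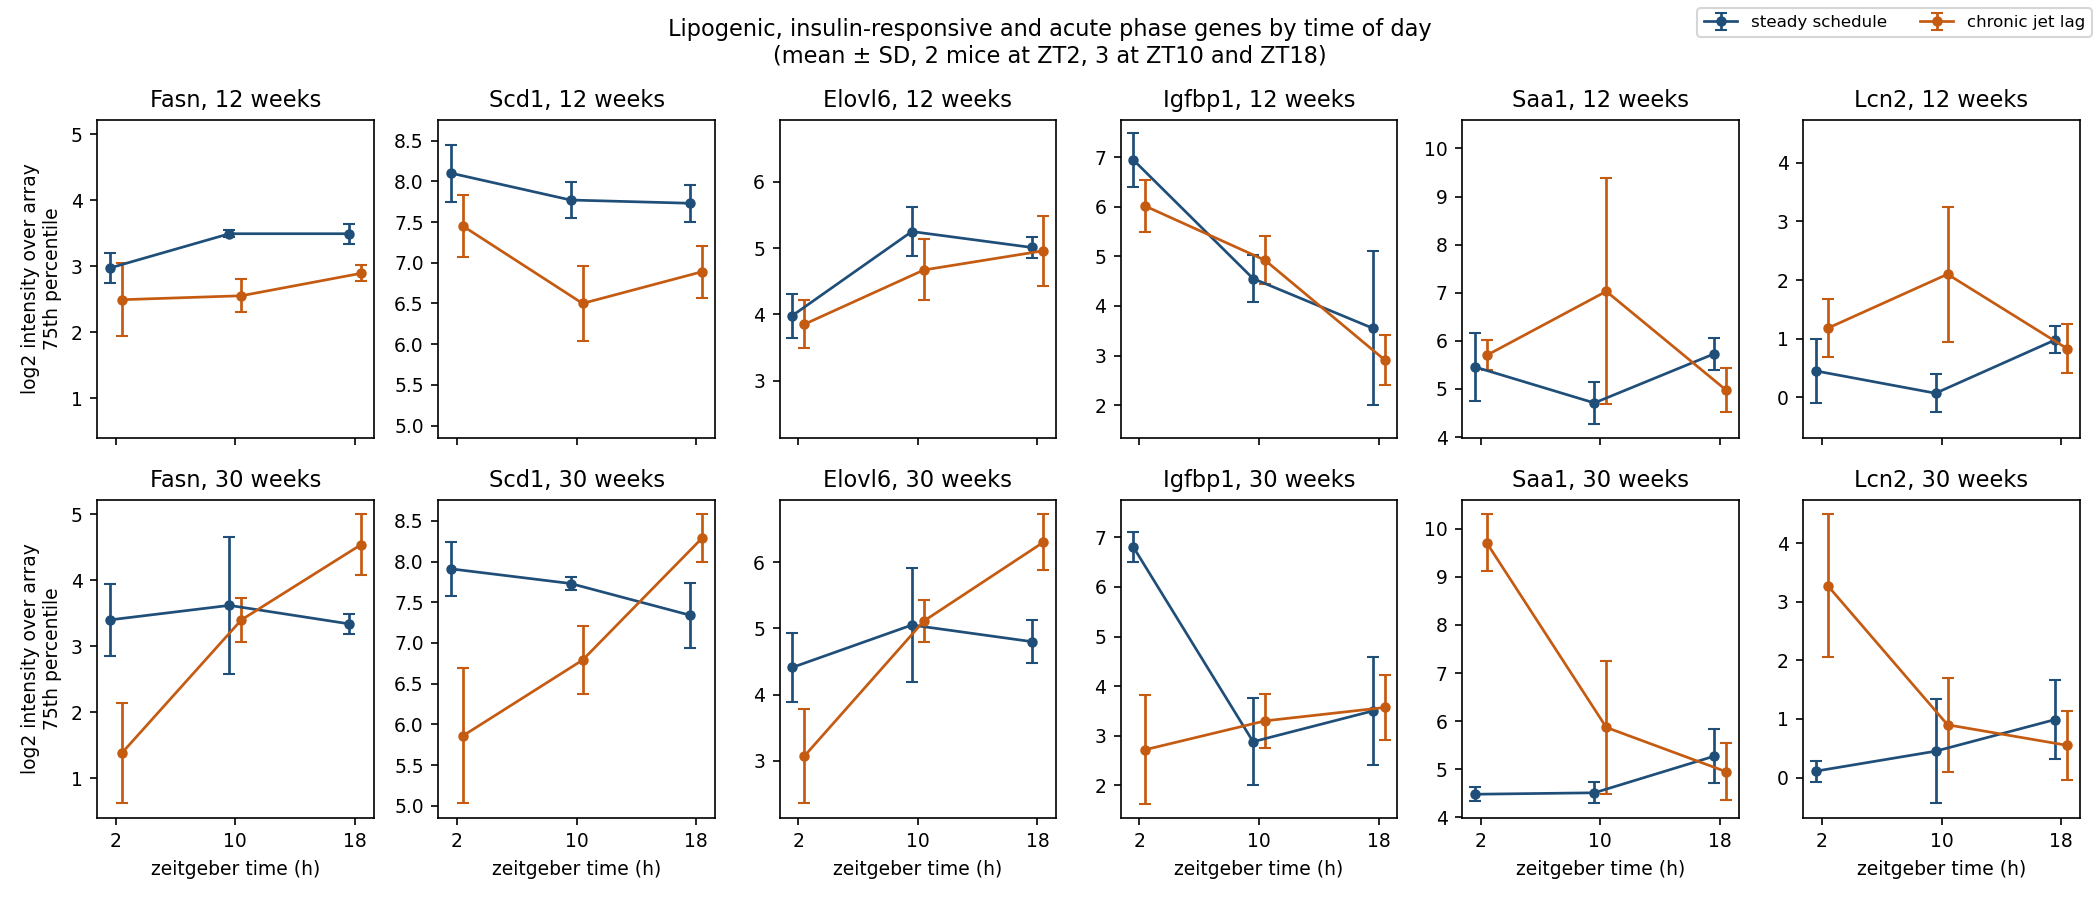
Levels of lipogenic (Fasn, Scd1, Elovl6), insulin-responsive (Igfbp1) and acute phase genes (Saa1, Lcn2), as log2 intensity over the array's 75th percentile, against zeitgeber time at 12 weeks (top) and 30 weeks (bottom). Points are group means with SD, with 2 mice at ZT2 and 3 at ZT10 and ZT18. At 30 weeks and ZT2, Scd1 fell by 2.18 and Igfbp1 fell by 4.17 in jet-lagged mice, while Saa1 was higher by 5.70.

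The schedules were next compared over the mean of the 3 times, which asks how the mean log2 level of each gene differed between schedules. A shallower trough raises this mean even where the peak is not higher. Dbp at 12 weeks averaged 4.76 in jet-lagged and 0.42 in steady mice at ZT2, but 5.46 and 6.83 at ZT10. In these comparisons rose and fell refer to the mean log2 level. At 12 weeks 8 core clock genes rose, while 11 genes of fatty acid and triglyceride synthesis and 7 of cholesterol synthesis fell. Dbp rose by 1.91 ± 0.25 (n = 8 against 8, adjusted p = 0.000199). Ciart was at least 1.54-fold higher and Per3, a period gene, at least 1.51-fold, since 2 and 1 of the 3 steady groups had no array well above background. At ZT10 the differences of Dbp, Ciart and Per3 had the opposite sign (adjusted p = 0.0786, 0.07 and 0.711). Of 22 core clock genes 8 rose, and adjusted over the list alone 10 rose and 3 fell. The list as a whole was higher (camera adjusted p = 0.000221, adjusted p = 0.213 with an estimated correlation). Of 32 genes of fatty acid and triglyceride synthesis 11 fell, and adjusted over the list alone 18 fell and 1 rose (camera adjusted p = 1.23e-13, adjusted p = 0.213 with an estimated correlation). Among them Scd1 changed by -0.91 ± 0.17, Acacb, the mitochondrial acetyl-CoA carboxylase, by -0.87 ± 0.18, and Acss2, an acetyl-CoA synthetase, by -0.77 ± 0.15. Pnpla5 was at least 2.01-fold lower and was well above background on 1 of 8 jet-lagged and 7 of 8 steady arrays. Of 26 genes of cholesterol synthesis 7 fell, and 10 adjusted over the list alone (camera adjusted p = 1.73e-09, adjusted p = 0.575 with an estimated correlation). The mevalonate decarboxylase Mvd changed by -0.94 ± 0.15.

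Smaller groups moved as well at 12 weeks. Of 31 glutathione and other NRF2 response genes 4 fell, and 5 adjusted over the list alone, among them the transferases Gstm4 (-0.48 ± 0.09) and Gsta4 (-0.34 ± 0.07). The list was lower (camera adjusted p = 0.00389, adjusted p = 0.575 with an estimated correlation). Of 31 ribosome biogenesis genes 3 rose, and 7 adjusted over the list alone, such as Polr1a, the large subunit of RNA polymerase I (0.47 ± 0.08). That list was higher (camera adjusted p = 0.000307, adjusted p = 0.762 with an estimated correlation). Of 30 proliferation genes 1 fell, the proliferation marker Mki67 (-0.74 ± 0.20), and 2 fell adjusted over the list alone (camera adjusted p = 0.000307, adjusted p = 0.663 with an estimated correlation). Of 20 heat shock genes 2 rose, the chaperones Dnajb1 (0.46 ± 0.11) and Hspa8 (0.31 ± 0.07), and 4 adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.923 with an estimated correlation). The 9 MHC class II genes were lower as a list (camera adjusted p = 0.026, adjusted p = 0.923 with an estimated correlation), with 0 called by limma, 0 adjusted over the list alone and 5 at unadjusted p under 0.05. Bile acid genes moved both ways, with 2 of 26 higher and 3 lower (4 and 5 adjusted over the list alone). Cyp7b1, the oxysterol hydroxylase of the alternative pathway, rose by 0.56 ± 0.14, whereas the bile salt export pump Abcb11 changed by -0.32 ± 0.06. In glucose metabolism 3 of 28 genes rose and 1 fell (5 and 2 adjusted over the list alone), and Pck1, the gluconeogenic carboxykinase, rose by 0.89 ± 0.20.

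Genes outside these lists also fell at 12 weeks. Chrna4, a nicotinic acetylcholine receptor subunit, was at least 4.64-fold lower (adjusted p = 0.000199) and was well above background on 3 of 8 jet-lagged and 8 of 8 steady arrays. Loxl4, a collagen crosslinking oxidase, was at least 2.74-fold lower and was well above background on 2 of 8 jet-lagged and 7 of 8 steady arrays. Aqp8, a water channel of the bile canaliculus, changed by -1.47 ± 0.16 (adjusted p = 4.51e-05). Hamp2, an iron-regulated hepcidin gene, changed by -1.48 ± 0.32, whereas Hamp, which encodes the circulating hepcidin, rose by 0.55 ± 0.11. Aatk, a kinase, rose by 0.97 ± 0.16 and Noct, a clock-regulated phosphatase, by 0.91 ± 0.23. In all 1008 genes were called, 451 higher and 557 lower, 36 of them by at least 2-fold. The lower share was 55.3%, 45.3% in the authors' table, 70.7% with the acinar-rich arrays left out and 70.5% without all ZT2 mice. The 12 pancreatic acinar markers had a median change of 1.42 (camera adjusted p = 0.0265, adjusted p = 0.923 with an estimated correlation), with 0 called by limma and 0 at unadjusted p under 0.05. Over both ages their mean was 1.07 in jet-lagged mice at ZT10 against -1.52 in steady mice. With the 10 acinar-rich arrays left out 345 genes were called, with no block 283 and without all ZT2 mice 501. Leaving out 1 mouse gave 409 (mouse 1 of the steady ZT2 group) to 1855 (mouse 1 of the jet-lagged ZT2 group).

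At 30 weeks 11 core clock genes rose, while 14 genes of cholesterol synthesis and 11 of fatty acid and triglyceride synthesis fell. Dbp rose by 2.16 ± 0.25 (n = 8 against 8, adjusted p = 4.97e-05) and Usp2, a clock-driven deubiquitinase, by 1.59 ± 0.22. Ciart was at least 3.17-fold higher and Per3 at least 1.85-fold. At ZT10 the group means of these genes were lower in jet-lagged than in steady mice. They were 5.72 against 6.92 for Dbp, 3.87 against 4.31 for Usp2, 0.02 against 1.06 for Ciart and -1.25 against -1.1 for Per3. Of 22 core clock genes 11 rose, and adjusted over the list alone 11 rose and 5 fell (camera adjusted p = 4.83e-08, adjusted p = 0.0652 with an estimated correlation). Of 26 genes of cholesterol synthesis 14 fell, and 20 adjusted over the list alone (camera adjusted p = 6.98e-19, adjusted p = 0.259 with an estimated correlation). The synthase Hmgcs1 changed by -1.17 ± 0.19 and Mvd by -1.09 ± 0.15. Of 32 genes of fatty acid and triglyceride synthesis 11 fell and 1 rose, and 12 and 2 adjusted over the list alone (camera adjusted p = 1.31e-06, adjusted p = 0.496 with an estimated correlation). Elovl3, a clock-regulated elongase, changed by -1.82 ± 0.30 and Acacb by -1.08 ± 0.18. Without the ZT2 mice this list pointed the other way (adjusted p = 0.22). Fatty acid oxidation moved the other way, with 4 of 42 genes higher and 1 lower, and 11 and 1 adjusted over the list alone (camera adjusted p = 2.05e-07, adjusted p = 0.496 with an estimated correlation). Cyp4a14, a fatty acid omega-hydroxylase, rose by 2.15 ± 0.53 and Cpt1a, the gate of mitochondrial import, by 0.44 ± 0.11, whereas the kinase Pdk4 changed by -0.94 ± 0.22.

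**Figure D3:**
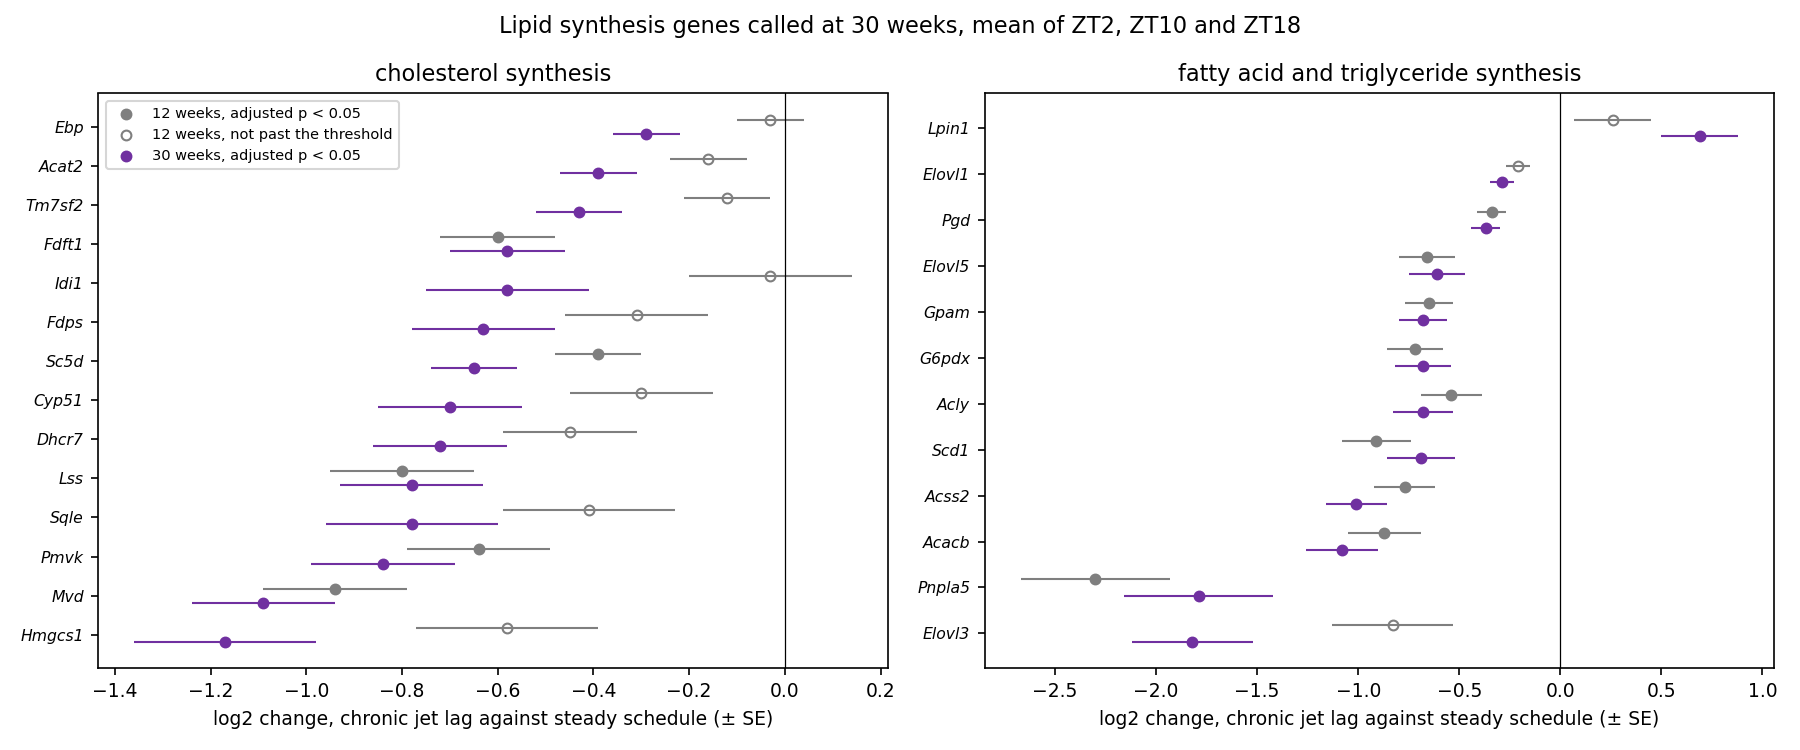
Changes of the genes of cholesterol synthesis (left) and of fatty acid and triglyceride synthesis (right) that passed the threshold at 30 weeks, between chronic jet lag and the steady schedule, over the mean of the 3 times. Points are log2 changes with SE at 12 weeks (grey) and 30 weeks (purple), filled where the adjusted p was under 0.05, n = 8 against 8 mice. For cholesterol synthesis 14 of 26 genes fell at 30 weeks.

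Endoplasmic reticulum chaperones, acute phase genes and a set of cell markers also moved at 30 weeks. Of 28 genes of the unfolded protein response 9 fell, and adjusted over the list alone 16 fell and 1 rose (camera adjusted p = 1.69e-07, adjusted p = 0.362 with an estimated correlation). Sdf2l1, a cochaperone, changed by -1.14 ± 0.21 and the chaperone Hsp90b1 by -0.36 ± 0.07. Of 31 acute phase genes 8 rose and 5 fell, and 12 and 6 adjusted over the list alone (camera adjusted p = 0.000915, adjusted p = 0.496 with an estimated correlation). Saa1 rose by 2.14 ± 0.41 and Lcn2 by 1.11 ± 0.30. Without the ZT2 mice that list pointed the other way (adjusted p = 0.40), as did Lcn2 (-0.14). Of 31 ribosome biogenesis genes 4 rose, and 11 rose and 1 fell adjusted over the list alone, such as Ppan (0.59 ± 0.14). The list was higher (camera adjusted p = 7.52e-05, adjusted p = 0.496 with an estimated correlation). Of 18 cholangiocyte markers 4 fell, and 5 adjusted over the list alone, led by the keratin Krt23 at -0.81 ± 0.18 (camera adjusted p = 0.00288, adjusted p = 0.51 with an estimated correlation). Of 12 red blood cell markers 4 fell, and 5 adjusted over the list alone, such as the globin Hba-a1 at -0.59 ± 0.13 (camera adjusted p = 0.00288, adjusted p = 0.496 with an estimated correlation). The 25 macrophage and Kupffer cell markers were higher as a list (camera adjusted p = 0.00856, adjusted p = 0.613 with an estimated correlation), with 0 called by limma, 0 adjusted over the list alone and 0 at unadjusted p under 0.05. Of 28 genes of glucose metabolism and insulin response 2 rose and 4 fell, and 3 and 6 adjusted over the list alone (camera adjusted p = 0.988). Irs2, an insulin receptor substrate, changed by -0.87 ± 0.19 and Igfbp1 by -1.21 ± 0.33, whose call was lost in 11 of 32 fits without 1 mouse. Without the ZT2 mice the change of Igfbp1 was 0.28.

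Chrna4 and Aqp8 fell at 30 weeks too. Chrna4 was at least 10.4-fold lower (adjusted p = 1.94e-06) and was well above background on 4 of 8 jet-lagged and 8 of 8 steady arrays, and Aqp8 changed by -1.70 ± 0.16 (adjusted p = 2.99e-06). Rnf125, a ubiquitin ligase, changed by -1.21 ± 0.15. Alas1, which starts haem synthesis, rose by 1.11 ± 0.25, and Por, the electron donor of cytochromes P450, by 0.83 ± 0.13. In all 1385 genes were called, 445 higher and 940 lower (67.9% lower), 78 of them by at least 2-fold. The lower share was 49.3% in the authors' table and 57% with the percentile taken over detected probes. The ages had separate control mice but 1 error estimate per gene for both. They shared 275 called genes, where independent lists would share 60.4. Of the 275, 273 had the same direction (75 higher, 198 lower). Across genes the changes at both ages correlated with r = 0.358 (rho = 0.297), and genes are not independent replicates. With the acinar-rich arrays left out 416 genes were called, with no block 738 and without all ZT2 mice 515. Leaving out 1 mouse gave 583 (mouse 1 of the jet-lagged ZT2 group) to 1638.

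At single times the groups held 2 or 3 mice. At 12 weeks 57 genes differed at ZT2 (21 higher, 36 lower), 418 at ZT10 (192 and 226) and 665 at ZT18 (232 and 433). At ZT18 the lower share was 65.1%, 53.4% with the percentile taken over detected probes and 45.3% with the acinar-rich arrays left out. At ZT2 the nuclear receptor gene Ppard changed by -1.83 ± 0.20 (n = 2 against 2, adjusted p = 7.21e-05), and the globin Hbb-bt rose by 1.42 ± 0.25. At ZT10 Cyp2b10, a xenobiotic-inducible P450, rose by 2.21 ± 0.43 and Lcn2 by 2.14 ± 0.50, while the lectin-like receptor gene Clec2h changed by -2.28 ± 0.46. Of the 12 acinar markers 0 were called by limma at ZT10, 9 had an unadjusted p under 0.05, and 8 were higher adjusted over the list alone. With marker covariates 0 genes were called by limma at ZT10 (2378 at unadjusted p under 0.05), and with the acinar-rich arrays left out 2. At ZT18 Nr1d1 was at least 6.06-fold higher and Ciart at least 7.75-fold higher in jet-lagged mice. Of 26 cholesterol synthesis genes 10 fell at ZT18 (18 adjusted over the list alone), with Mvd at -1.76 ± 0.25 and the phosphomevalonate kinase Pmvk at -1.27 ± 0.26. Herpud1, a component of endoplasmic reticulum degradation, rose by 0.89 ± 0.14, and the interferon-induced GTPase Ifi47 changed by -1.13 ± 0.19. Of the genes called at both ZT10 and ZT18, 18 had the same direction and 31 the opposite one. Without 1 mouse the counts ran from 9 to 680 at ZT2, 13 to 529 at ZT10 and 319 to 744 at ZT18.

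At 30 weeks 316 genes differed at ZT2 (116 higher, 200 lower), 157 at ZT10 (47 and 110) and 812 at ZT18 (392 and 420). At ZT10 the lower share was 70.1%, and 50.7% with the percentile taken over detected probes. At ZT2, 14 of 32 genes of fatty acid and triglyceride synthesis fell, and adjusted over the list alone 20 fell and 1 rose. Acacb changed by -2.19 ± 0.37. In the same 2 jet-lagged mice 11 of 31 acute phase genes rose and 1 fell at ZT2, and 15 and 1 adjusted over the list alone. Chrna4 was at least 32.2-fold lower at ZT2. At ZT10 Arntl rose by 2.75 ± 0.50 and Nr0b2, the bile acid-induced repressor SHP, 2.83-fold (adjusted p = 0.0436), while the cyclin Ccnd1 changed by -1.19 ± 0.22. At ZT18 Rgs16, a regulator of G protein signalling, rose by 4.98 ± 0.94 and Nr1d1 by 4.24 ± 0.56 (well above background on 1 of 3 steady arrays), while Elovl3 changed by -3.11 ± 0.51. Of 31 ribosome biogenesis genes 6 rose and 1 fell at ZT18 (12 and 1 adjusted over the list alone). Lpin1, a phosphatidate phosphatase, rose by 2.48 ± 0.33, and the cell cycle genes Ccne1 and Rrm2 by 1.96 ± 0.28 and 1.48 ± 0.26. Genes called at both ZT2 and ZT18 numbered 81, of which 78 had the same direction. With slide as a fixed block the counts were 141, 6 and 384. At ZT18 the lower share was 51.7%, 65.9% with slide as a fixed block, 44.8% with no block and 43.8% in the authors' table. Without 1 mouse they ran from 61 to 477 at ZT2, 0 (1889 at unadjusted p under 0.05) to 449 at ZT10 and 269 to 925 at ZT18.

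The ages were compared within each schedule, which asks what changed from 12 to 30 weeks. In steady mice the zinc finger gene Zfp979 rose by 2.32 ± 0.14 (n = 8 against 8, adjusted p = 1.72e-09) and the homeobox gene Irx1 by 1.66 ± 0.15. Cyp2b10 rose by 1.44 ± 0.26. Hamp2 changed by -1.79 ± 0.32 whereas Hamp rose by 0.66 ± 0.11, and the trefoil factor Tff3 changed by -1.24 ± 0.23. In all 199 genes were called, 125 higher and 74 lower. The 32 interferon response genes were lower as a list (camera adjusted p = 1.47e-11, adjusted p = 0.506 with an estimated correlation), with 0 called by limma, 8 lower adjusted over the list alone and 15 at unadjusted p under 0.05. The 30 proliferation genes were lower as a list (camera adjusted p = 6.16e-05, adjusted p = 0.555 with an estimated correlation), with 0 called by limma, 0 adjusted over the list alone and 8 at unadjusted p under 0.05. The 23 lipid droplet genes were higher (camera adjusted p = 0.00011, adjusted p = 0.506 with an estimated correlation), with 1 called, the lipid storage gene Fitm1 (0.69 ± 0.16), and 4 adjusted over the list alone. The 23 endothelial markers were higher (camera adjusted p = 0.000493, adjusted p = 0.555 with an estimated correlation), with 2 called, Clec4g and Fcgr2b, and 6 higher and 1 lower adjusted over the list alone. The 26 male-biased genes were lower (camera adjusted p = 0.00361, adjusted p = 0.919 with an estimated correlation). Of these 1 rose and 2 fell, and 1 and 2 adjusted over the list alone, with the P450 Cyp4a12a at -0.53 ± 0.12. Without all ZT2 mice 89 genes were called (78 higher, 11 lower), and with the acinar-rich arrays left out the balance turned (78 higher, 111 lower).

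In jet-lagged mice the same comparison of ages called 1152 genes, 522 higher and 630 lower. The older of these mice had also been jet-lagged for longer, so the comparison cannot tell age from duration. A larger count than in steady mice does not test whether the schedules differed. Zfp979 rose by 2.39 ± 0.14 and the protease inhibitor Serpine2 by 1.45 ± 0.16. Of 23 lipid droplet genes 7 rose, and 8 adjusted over the list alone (camera adjusted p = 6.11e-07, adjusted p = 0.262 with an estimated correlation). Cidea, a lipid droplet fusion protein, rose by 2.32 ± 0.57 and the perilipin Plin4 by 0.93 ± 0.23. Of 32 interferon response genes 10 fell, and 13 adjusted over the list alone, led by Ifi44 at -0.93 ± 0.16 (camera adjusted p = 1.03e-06, adjusted p = 0.719 with an estimated correlation). Of 42 fatty acid oxidation genes 3 rose, and 13 adjusted over the list alone (camera adjusted p = 7.77e-06, adjusted p = 0.719 with an estimated correlation). They were Fgf21, a fasting hormone (1.20 ± 0.34), Crat and Acaa1b. Of 28 genes of the unfolded protein response 6 fell, and 11 adjusted over the list alone, such as Pdia3 at -0.36 ± 0.06 (camera adjusted p = 6.26e-05, adjusted p = 0.719 with an estimated correlation). Of 26 male-biased genes 1 rose and 3 fell, and 2 and 11 adjusted over the list alone (camera adjusted p = 0.0014, adjusted p = 0.719 with an estimated correlation). Bcl6, a repressor that favours male liver expression, changed by -1.75 ± 0.35, and the female-biased transporter Slc22a27 was at least 1.77-fold higher. Of 12 red blood cell markers 5 fell, and 5 adjusted over the list alone (camera adjusted p = 0.000488, adjusted p = 0.719 with an estimated correlation).

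Among the other lists compared between ages in jet-lagged mice, MHC class II and macrophage markers were higher (camera adjusted p = 0.00579 for both, adjusted p = 0.719 for both with an estimated correlation). Limma called 0 of 9 and 1 of 25 members, and 0 and 1 adjusted over the list alone (3 of the 9 at unadjusted p under 0.05). The called macrophage marker was Cd9, a tetraspanin (0.40 ± 0.07). Periportal hepatocyte genes were lower, with 1 of 20 higher and 3 lower, and 1 and 7 adjusted over the list alone (camera adjusted p = 0.0439, adjusted p = 0.719 with an estimated correlation). NRF2 response genes were higher, with 3 of 31 called, and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0492, adjusted p = 0.719 with an estimated correlation). The comparisons of ages in the 2 schedules shared 135 called genes, where independent lists would share 9.9, and all 135 had the same direction. The lower share was 54.7%, 65.5% with normexp, 46.5% with quantile normalisation, 45.1% with the percentile taken over detected probes and 48.6% in the authors' table. With the acinar-rich arrays left out 103 genes were called and with no block 559. Without 1 mouse the count ran from 578 (mouse 1 of the jet-lagged ZT2 group at 30 weeks) to 1876 (mouse 1 of that group at 12 weeks).

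Whether the difference between schedules changed from 12 to 30 weeks was tested as schedule by age. The older jet-lagged mice had also been jet-lagged for longer, so this test cannot tell age from duration. Klf16, a Krüppel-like transcription factor, differed by 0.77 ± 0.12, from -0.34 ± 0.09 at 12 weeks to 0.42 ± 0.09 at 30 weeks (adjusted p = 0.049). Abhd18, a hydrolase-domain protein, differed by -0.61 ± 0.10, from 0.18 ± 0.07 to -0.43 ± 0.07 (adjusted p = 0.049). These 2 genes passed the adjusted threshold in limma, and 2940 had an unadjusted p under 0.05. In the 7 lists called by camera 0 members were called by limma over all genes. Proliferation genes had a more positive difference at 30 weeks (camera adjusted p = 1.34e-05), and so did fatty acid oxidation (0.00032) and MHC class II genes (0.0107), each with adjusted p = 0.758 with an estimated correlation. Red blood cell markers (9.04e-05), the unfolded protein response (0.00134), heat shock (0.00156) and cholesterol synthesis (0.041) had a more negative one, again each with adjusted p = 0.758 with an estimated correlation. Without all ZT2 mice the red blood cell and cholesterol synthesis lists pointed the other way (adjusted p = 0.20 and 0.46). At unadjusted p under 0.05 there were 4 proliferation, 7 fatty acid oxidation, 0 MHC class II, 6 red blood cell, 10 unfolded protein response, 9 heat shock and 6 cholesterol synthesis genes. Adjusted over the list alone, 4 red blood cell and 4 heat shock genes were lower and 3 fatty acid oxidation genes higher. Without 1 mouse the count ran from 0 (18 fits, with 2274 to 3109 at unadjusted p under 0.05) to 455, the latter without mouse 1 of the jet-lagged ZT2 group at 12 weeks.

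**Figure D4:**
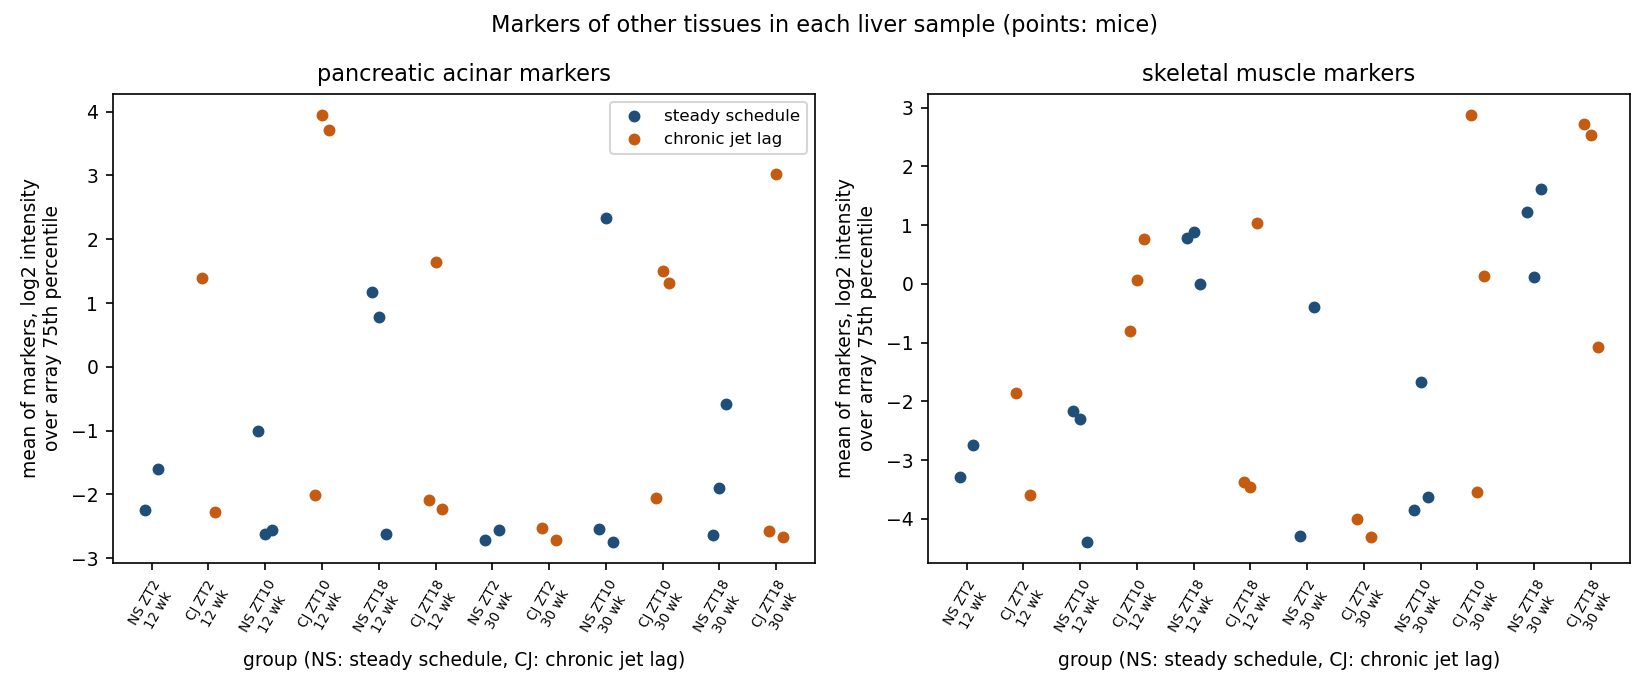
Mean level of pancreatic acinar markers (left, 12 genes) and skeletal muscle markers (right, 19 genes) in each liver sample, as log2 intensity over the array's 75th percentile, by group. Points are mice, and the groups run from 12 to 30 weeks and from ZT2 to ZT18. Over both ages the acinar mean in jet-lagged mice at ZT10 was 1.07, against -1.52 in steady mice at ZT10, and the muscle mean in steady mice at ZT18 was 0.77.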

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

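The tests of the acute phase genes, of the marker genes and of the size of the clock interactions were chosen only after the result was seen. The results singled out here are tested changes of the difference between schedules with time of day or with age, which goes with the duration of jet lag. At 12 weeks 446 genes and at 30 weeks 431 genes had a schedule by time of day interaction. Of the 22 core clock genes these included 12 and 13, among them Dbp and Arntl. At 30 weeks they also included 11 of 32 genes of fatty acid and triglyceride synthesis, among them Fasn and Scd1, and 7 of 31 acute phase genes, among them Saa1 and Lcn2. For schedule by age 2 genes passed, Klf16 and Abhd18.

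The mice of each comparison were also regrouped at random, with 100 splits each, the real one included. For the schedules over the mean of the 3 times, the real split called 1008 genes and another at most 709 at 12 weeks. At 30 weeks these counts were 1385 and 467 (1 split as large each, the real one). Chance could be excluded there for some difference between schedules. The regroupings also mixed schedule differences that vary with time of day, so they did not test the mean alone. With the same limit it could be excluded for some difference between the ages, with 199 and 68 in steady mice and 1152 and 119 in jet-lagged mice. For time of day chance could be excluded as well. The real and highest other counts in steady mice were 4052 and 2014 at 12 weeks and 2587 and 1384 at 30 weeks. In jet-lagged mice they were 1308 and 1125 at 12 weeks and 857 and 553 at 30 weeks. For the interactions of schedule with time of day 2 of 100 splits were as large at each age, the real one included, a share under 0.05. The real split called 446 genes and another 493 at 12 weeks, and 431 and 833 at 30 weeks. These regroupings also mixed the difference between schedules over the mean of the 3 times, so they did not test the interaction alone. Chance is therefore not excluded for the interactions. A regrouping that swaps the schedules at only 1 time turns the mean difference into an apparent interaction. Larger counts in a regrouping can therefore come from the regrouping itself. A structure of the samples was looked at only through the markers. At 12 weeks the split with 493 genes ranked 7 of 100 in muscle marker difference (4.45, against 5.45 in the real split) and 23.5 in acinar difference. At 30 weeks the split with 833 genes ranked 63.5 and 41.5. For the schedules at 12 weeks the split with 709 genes ranked 6 in acinar difference (1.45, against 1.59 in the real split) and 89 in muscle difference. There the regrouping cannot tell the schedule from pancreatic RNA. For schedule by age 4 splits were as large, and 1 of them called 582 genes against 2 (its acinar and muscle marker differences ranked 40 and 50 of 100). These regroupings were drawn separately at each age, so they mixed in the schedule difference shared by both ages. Neither chance nor a structure of the samples can be judged from that count. With 3 mice against 3 the 10 splits are too few for a share under 0.05. There 418 genes were called against at most 1 at ZT10 and 665 against 2 at ZT18 at 12 weeks, and 157 against 1 and 812 against 0 at 30 weeks.

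The 1st pattern was the smaller daily range of core clock genes such as Dbp, Nfil3 and Arntl under jet lag. Some profiles also moved in time, while Dbp stayed highest at ZT10. At 12 weeks Nr1d1 averaged 1.67 at ZT2 and -0.81 at ZT10 in jet-lagged mice, against 0.24 and 0.93 in steady mice. Cry1 averaged -3.23 and -1.9 there, against -1.78 and -3.47. At 30 weeks both genes moved in the same way. A phase shift shared by the jet-lagged mice was not tested. Against pancreas or muscle RNA and against slide differences as the whole cause stood the sizes, since the median interaction range of the called clock genes went from 2.86 to 2.86 with marker covariates and 2.93 with slide as a fixed block at 12 weeks and from 3.21 to 2.99 and 2.90 at 30 weeks (93.3% and 90.5% kept at the age with the smaller share), and was 3.04 and 3.65 with the acinar-rich arrays left out. The tests on calls left both explanations open, since error and adjustment changed, and 72% of the calls stayed with marker covariates (5 of 12 and 13 of 13 at the 2 ages), 52% with slide as a fixed block (8 of 12 and 5 of 13), and 2 of 12 and 0 of 13 in limma on the 22 arrays not rich in acinar markers (12 and 13 at unadjusted p under 0.05). Mice of a jet-lagged group at different clock phases may add to the pattern. Over 19 clock genes the median ratio of within-group SD, jet-lagged over steady, was 1.38 (1.1 to 1.55 with 1 mouse left out, 1.03 over all genes). The ratio was above 1 for 12 of the 19 genes and ran from 0.44 for Nr1d1 to 3.17 for Usp2. The median lay between the bounds set for a decision. Flattened clocks in each mouse and mice at different phases cannot be told apart from 2 or 3 mice per group, and jet lag itself stays among the open explanations.

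The 2nd pattern was the high level of Saa1, Saa2 and Lcn2 in the 2 jet-lagged mice at ZT2 and 30 weeks. A slide difference as the cause was argued against, since the highest of 6 other arrays on their slides lay 3.14 log2 units lower in the mean of Saa1 and Saa2 (a difference of -3.14, 6.10 against 9.25). Of the other 14 jet-lagged mice 3 also lay above every steady mouse (highest 6.08) in that mean, all at ZT10, with 6.10, 9.63 and 7.49, the first by a small margin, and the highest at ZT18 was 5.54. So an acute phase response in single jet-lagged mice may explain part of the pattern, but it was not seen at every time of day. Whether time of day, infection or the shift itself raised the level was not tested, and with 2 mice at ZT2 a part for the time of day stays open.

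The 3rd pattern was pancreatic and skeletal muscle genes among those that varied between livers. Pancreatic tissue taken along with some livers is a candidate source, since the 12 acinar markers moved together over arrays once group means were removed (median pairwise r 0.94, lowest 0.83). Ctrb1, a chymotrypsinogen, averaged 4.08 in jet-lagged mice at ZT10 and 12 weeks against 0.85 in steady mice, and Clps, the colipase, 3.01 against -0.70. Muscle is a candidate source in the same way, with a median r of 0.86 over 19 markers, although the lowest pair was at -0.12 and 2 and 8 muscle markers passed for time of day in steady mice at 12 and 30 weeks. More pancreatic RNA under jet lag was left open, with a schedule difference of 1.22 and a two-sided permutation p = 0.12 (1e+05 permutations), and the labels do not say whether other tissue was taken along.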

How the results depend on the processing

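The tests with the percentile over detected probes, with acinar-rich arrays left out, with marker covariates and with ZT2 arrays left out were chosen only after the result was seen. Comparisons are abbreviated here. J12 and J30 are the schedules compared over the mean of the 3 times at 12 and 30 weeks, and J12 ZT2 is the same at 1 time. D is time of day within steady (S12, S30) or jet-lagged mice (L12, L30), I12 and I30 are its interactions with schedule, AS and AL compare the ages within steady and jet-lagged mice, and JA is schedule by age. The text rests on 180 gene results and 41 list results besides the counts. Some of the 180 are ranges over the 3 times, which have no sign and could not reverse. With each mouse left out in turn 0 of the 180 reversed in sign and 63 lost their limma call at least once. Under the alternatives for the signal the genes that stayed on their side were 164 of 180 with normexp, 174 with quantile normalisation, 157 with no filter on dim probes and 177 with the percentile over detected probes. For the blocks they were 149 with no block, 141 with slide as a fixed block and 172 with scan day as a random block. With the acinar-rich arrays left out 93 of 180 genes and 21 of 41 lists stayed, and with ZT2 arrays left out 51 of 92 genes and 28 of 41 lists. With marker covariates 160 of 180 genes stayed. Between 43.4% and 58.1% of probes per array were well above background, and dimmer ones limit what can be measured. No scaling moved the median of all genes by over 0.1.

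Counts that moved by over 1.5 times follow by setting, and the cause was not tested except where fewer arrays or genes are named. With normexp they were J12 ZT10 730, J12 ZT18 439, AS 129, AL 1785 and JA 0 (3296 at unadjusted p under 0.05 in limma). With quantile normalisation JA was 5, with 11 lists. With no filter on dim probes, which adds tests, J12 was 515, J30 864, J12 ZT10 210, J12 ZT18 344, J30 ZT2 188, J30 ZT10 47, J30 ZT18 497, I12 214, I30 215 and JA 0 (3562 unadjusted), with 8 lists for AS and 12 for JA. With probes well above background on all 32 arrays, fewer genes were tested, and J12 ZT2 was 34, AS 131 and JA 9, with 11 lists for JA. With the mean of a gene's probes JA was 0 (2817 unadjusted), with trend and robust variances 7 with 11 lists, and with the percentile over detected probes 4.

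With no block J12 was 283, J30 738, J12 ZT2 36, J12 ZT10 186, J30 ZT10 103, AS 108, AL 559 and JA 0 (2058 at unadjusted p under 0.05 in limma). With slide as a fixed block J12 ZT2 was 17, J12 ZT10 80, J12 ZT18 225, J30 ZT2 141, J30 ZT10 6, J30 ZT18 384, D S12 2685, D S30 1501, D L12 550, D L30 492, I12 85, I30 59, AS 121 and JA 1. With scan day as a random block J30 ZT10 was 90 and JA 0 (2774 unadjusted), and with the replicate block JA was 0 (2947). With the authors' table and no block J12 was 2115, J12 ZT10 1590, J30 ZT2 676, J30 ZT10 493, J30 ZT18 1722, D S30 3886, D L12 2174, D L30 1649, I12 690, I30 1110, AS 128 and JA 95, with 4 lists for J12. The cause of these moves was not tested. Camera with an estimated correlation called 0 lists in each of the 5 comparisons (2, 3, 2, 1 and 0 at unadjusted p under 0.05).

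With the 10 acinar-rich arrays left out 22 remained. Most counts fell but J12 ZT2 and JA grew, and the cause was not tested. J12 was 345, J30 416, J12 ZT2 522, J12 ZT10 2, J12 ZT18 150, J30 ZT2 145, J30 ZT10 19, J30 ZT18 225, D S30 1710, D L12 462, D L30 216, I12 181, I30 22, AL 103 and JA 11, with 4 lists for J12, 3 for AS and 3 for AL. Groups left with 1 array are assumed to vary like the others. With marker covariates J12 was 635, J12 ZT10 0 (2378 at unadjusted p under 0.05 in limma), J12 ZT18 230, J30 ZT10 31, D S12 2577, D S30 1638, D L30 232, I12 36, I30 255 and JA 0 (2898). With ZT2 arrays left out J12 was 501, J30 515, AS 89, AL 571 and JA 0 (2259), with 18 lists for AL, and the cause was not tested beyond the smaller number of arrays. The acinar marker list of J12 reversed with those arrays left out (adjusted p = 0.85) and with marker covariates (0.86). Without ZT2 arrays Lcn2 (-0.14) and Igfbp1 (0.28) reversed in J30, and so did the lists of fatty acid and triglyceride synthesis (adjusted p = 0.22) and acute phase genes (0.40) in J30 and those of cholesterol synthesis (0.46) and red blood cells (0.20) in JA.

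The share of lower genes in J30 was 67.9%, 49.3% in the authors' table and 57.0% with the percentile over detected probes. In J12 it was 55.3%, 45.3% in the authors' table, 70.7% with acinar-rich arrays left out and 70.5% with ZT2 arrays left out. In AL it was 54.7%, 65.5% with normexp, 46.5% with quantile normalisation, 45.1% with the percentile over detected probes, 48.6% in the authors' table, 40.8% with acinar-rich arrays left out and 39.8% with ZT2 arrays left out. At single times it was 54.1% in J12 ZT10 and 51.7% in J30 ZT18, and 45.8% and 43.8% in the authors' table. In AS it was 37.2%, 58.7% with acinar-rich arrays left out and 12.4% with ZT2 arrays left out.

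With 1 mouse left out the counts had these ranges, and a lone mouse left at ZT2 is assumed to vary like the other groups. Mice are named by group and number. J12 ran from 409 (steady ZT2 mouse 1) to 1855 (jet-lagged ZT2 mouse 1), with 440 and 415 without mouse 2 of these groups, 612 without steady ZT10 mouse 3, 546 without jet-lagged ZT10 mouse 3 and 608 without jet-lagged ZT18 mouse 2. J30 ran from 583 (jet-lagged ZT2 mouse 1) to 1638, with 755 and 864 without steady ZT2 mice 1 and 2. J12 ZT2 ran from 9 (steady mouse 1) to 680 (jet-lagged mouse 1), with 116 without jet-lagged mouse 2. J12 ZT10 ran from 13 (steady mouse 3) to 529, with 260 without steady mouse 2 and 36 and 263 without jet-lagged mice 2 and 3. J12 ZT18 ran from 319 (jet-lagged mouse 1) to 744, with 372, 369 and 393 without steady mice 1, 2 and 3 and 321 without jet-lagged mouse 2. J30 ZT2 ran from 61 (steady mouse 1) to 477 (jet-lagged mouse 2), with 105 without steady mouse 2 and 78 without jet-lagged mouse 1. J30 ZT10 ran from 0 (steady mouse 1, 1889 at unadjusted p under 0.05 in limma) to 449 (steady mouse 3), with 13 without steady mouse 2 and 72 and 48 without jet-lagged mice 1 and 2. J30 ZT18 ran from 269 (steady mouse 2) to 925, with 511 and 439 without steady mice 1 and 3 and 423 and 404 without jet-lagged mice 2 and 3.

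D ran from 2914 to 4301 in S12, 1940 to 2778 in S30, 499 (jet-lagged ZT2 mouse 2) to 1538 in L12 and 320 (jet-lagged ZT2 mouse 2) to 955 in L30, with 556 in L30 without jet-lagged ZT18 mouse 2. I12 ran from 183 (steady ZT10 mouse 3) to 774 (jet-lagged ZT2 mouse 1), with 239 without jet-lagged ZT10 mouse 2, 291 without steady ZT18 mouse 1 and 282 without jet-lagged ZT18 mouse 2. I30 ran from 245 (steady ZT18 mouse 2) to 588, with 266 without steady ZT2 mouse 2, 260 without steady ZT10 mouse 2, 285 without jet-lagged ZT10 mouse 3 and 282 without steady ZT18 mouse 3. AS ran from 135 to 212. AL ran from 578 (jet-lagged ZT2 mouse 1 at 30 weeks) to 1876 (jet-lagged ZT2 mouse 1 at 12 weeks), with 652 without mouse 2 of the latter group. JA ran from 0 to 455 (jet-lagged ZT2 mouse 1 at 12 weeks), and 18 of the 32 fits gave 0 in limma (2274 to 3109 at unadjusted p under 0.05). JA was 27 without jet-lagged ZT2 mouse 2 at 12 weeks, 40 without jet-lagged ZT2 mouse 2 at 30 weeks, 22 without steady ZT18 mouse 1 at 12 weeks, and 1 to 5 in the other fits.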

Other observations

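The test of mouse numbers was chosen only after the result was seen, and the lists below were set before the data were examined. Xenobiotic response genes moved both ways at 30 weeks over the mean of the 3 times, with 4 of 27 higher and 3 lower, and 4 and 10 adjusted over the list alone (camera adjusted p = 0.259, 0.602 with an estimated correlation). Cyp2c55 changed by -0.68 ± 0.18 and the transferase Gstt1 by -0.39 ± 0.08, and at ZT2 Gsta1 changed by -1.41 ± 0.33 (n = 2 against 2, limma). Without mouse 1 of the jet-lagged ZT2 group Gsta1 was at -0.81 and without mouse 2 at -2.01, and its call was lost in 3 fits without 1 mouse. Of 20 periportal hepatocyte genes 1 rose and 3 fell, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.384), namely the cadherin Cdh1 (-0.48 ± 0.13), the urea cycle gene Ass1 (-0.44 ± 0.09) and the histidase Hal (-0.38 ± 0.10). Of 30 stellate cell and fibrosis genes 2 fell at both ages, and 2 adjusted over the list alone at each (camera adjusted p = 0.175 and 0.454). They were Col4a1 (-0.31 ± 0.08 at 12 weeks and -0.40 ± 0.08 at 30 weeks) and Pdgfrb (-0.27 ± 0.06 and -0.28 ± 0.06).

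Genes of liver tumours and fetal liver (27 measured) were also compared between the schedules. At 12 weeks limma called 0 of them (5 at unadjusted p under 0.05, camera adjusted p = 0.839). At 30 weeks 1 rose, Wfdc2 (0.67 ± 0.17), and 1 fell, Sox9 (-0.49 ± 0.14, camera adjusted p = 0.14). Between the ages in jet-lagged mice Wfdc2 rose by 0.93 ± 0.17 and Tff3 changed by -1.20 ± 0.23 (camera adjusted p = 0.175). In the same comparison Rhbg, a pericentral ammonium transporter, changed by -0.82 ± 0.12, and Jchain, the joining chain of immunoglobulins, rose by 1.23 ± 0.22. Deviations from group means of mice with the same number in other groups had a median r of -0.012 over 160 pairs, against 0.006 over 308 pairs with other numbers and 0.115 over 48 pairs on the same slide.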
